A study of Mus musculus with 83 samples.

How the data were processed

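The series followed mouse embryonic stem cells (the Bry-GFP and ZX1 lines, per the labels) through differentiation in culture, with 83 samples in 32 groups. The base medium, FAB, held bFGF (6 ng/ml), Activin A (8 ng/ml) and BMP4 (1 ng/ml). FAB+V added VEGF (5 ng/ml, from day 2), and FAB+P added PDGFAA at a dose not given in the sources used here. Cells were sorted on PDGFRα (P) and FLK1 (F, the product of Kdr). RNA-seq covered 14 libraries of sorted populations in FAB+V (day 4 P+F-, P+F+ and P-F+, day 8 P+F+ and P-F+) and 23 libraries of P+F+ cells in 3 media at days 4, 6 and 8. ATAC-seq, which reads open chromatin by transposase insertion, covered a time course of 27 libraries and a comparison of media with 10 libraries. ChIP-seq for H3K27ac, a histone mark of active enhancers and promoters, came with 9 samples, 3 of them inputs. Groups and replicate numbers were taken from the sample titles and characteristics. The labels do not say whether the sort given for days 6 and 8 is the day 4 sort or a later one. Kdr RNA was at only 4.4 ± 1.32 TPM (SD, n = 3) in day 6 FAB cells labelled P+F+. The later labels may thus not give the receptors carried on that day, and RNA alone cannot settle this.

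For RNA, the authors deposited per-gene TPM, per the file headers, from reads on mm10; TopHat2 2.1.1 and StringTie are named in the submitters' processing notes, with RefSeq transcripts as features. The table lists 30455 transcript lines for 23337 genes, and each gene's TPM is repeated on its transcripts' lines, so 1 value per gene was kept; these sum to 1000000 in every library. TPM keeps no sequencing depth, so the depth of the RNA libraries is unknown here. The genes with a TPM of at least 1 numbered 11498 to 12991 per library (median 12264). For ATAC, the authors deposited read counts in 267763 regions of 400 bp and, per the file headers, a fold enrichment over background per region and library, which is a ratio; Bowtie2 2.3.0, SAMtools 0.1.19, MACS2 and deepTools are named in the processing notes. Of the region centres, 17.7% coincide with a deposited summit. The summit lists hold, per library, 1 bp positions with a −log10 q-value as the authors' peak caller wrote it. The 3 H3K27ac lists hold, per the authors' deposited peaks, a fold enrichment (a ratio), −log10 p and −log10 q, with 2 ChIP libraries and 1 input seemingly pooled per list. The authors also deposited tables of their own comparisons, with log2 fold changes, p-values and FDR; edgeR 3.16.5, limma 3.30.13 and R 3.3.2 are named in the processing notes, and which ATAC libraries entered is not given in the sources used here. No column of per-sample values was left without a sample.

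The deposited RNA values are TPM and not counts, so the design's provision for normalized values was used: limma 3.58.1 with an intensity trend in R 4.3.3 on log2(TPM + 1), over genes with a mean of at least 1 TPM in at least 1 group of the experiment. All groups of an experiment entered 1 fit, and calls have a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and a group whose libraries are all at 0 is given as listed at 0 without a fold. Means carry the SD over libraries, and fold changes their SE. Of the gene symbols, 23091 matched a biotype and 246 did not. Fixed gene lists (15, written before the data were examined) were tested with fry, whose p tests whether a list's genes move, on balance, in 1 direction, with adjustment over the 15 lists of a comparison; it does not compare a list with other genes. The lists hold sort genes, hematoendothelial transcription factors, endothelial genes, erythroid and blood genes, cardiac transcription factors, cardiac contractile genes, nascent mesoderm, paraxial mesoderm, pluripotency, endoderm, neurectoderm, smooth muscle and mesenchyme, growth factor response, proliferation and stress genes. Some were written because the sorts could hold other cell types, and the stress list as a check of RNA or cell quality.

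ATAC counts were tested with edgeR 4.0.16 (TMM factors, filterByExpr, a trended dispersion, glmQLFit and glmQLFTest), with the time course and the media as separate fits of 223565 and 134424 regions. FAB+V replicates 4 and 5 stand with the media libraries, as in the series' design text. Reads in regions ranged from 1947191 to 9276426 per library (median 4316348), with a median of 3 to 15 reads per region, so single regions carry wide counting error. Counts in 3 libraries that sum to 0 are set against a floor of 3 counts over the group; ratios of small counts carry 95% counting intervals, which cover counting error only, as do the Wilson intervals of shares. Regions were assigned to the nearest transcription start (TSS) within 100 kb in the transcript coordinates of the deposited RNA table. Coordinates are mm10 and 1-based. Within 1 kb of a TSS lie 10.7% of regions, 78.1% lie within 100 kb, and 47.9% have their centre inside a transcript.

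Sets of genes or regions called between sorts were then tested between media, in libraries that the calling did not use, by fry (for regions added after the data were seen) and by the percentile of their median log2 fold change among 10000 random sets matched on mean level. A gene list was set against 10000 random lists matched on the number of assigned regions, by the share of its genes with a changed region. Overlap with an H3K27ac peak meant at least 1 bp, with peaks at a fold enrichment of at least 5 in each list, because 2 of the lists hold none below that. Summits were called shared within 100 bp. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for joins, sets and plots.

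Genes named in the text follow a rule fixed at the same stage as the lists. Per RNA comparison they are Pdgfra, Kdr and Etv2, then at most 4 called members of each list by adjusted p (or the member with the highest mean where none was called), then the 4 largest increases and decreases among called protein-coding genes whose groups do not overlap and whose mean reaches 5 TPM in a group. Per ATAC comparison they are the called region with the smallest adjusted p of each of 20 listed regulators, at most 8, and the 3 largest changes each way with non-overlapping groups and a mean of at least 2 CPM. The report names a part of these.

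Each model was tested on simulated data with 100 items changed at each fold. Changes were planted only in genes or regions above a minimum mean TPM or read count, so recovery at lower levels is not covered. For day 4 P-F+ against P+F+ (14298 genes), 71% of log2 changes of 1 and 94% of log2 changes of 2 were recovered, with 6.8% false calls; for day 8, 71% and 92%, with 8.4%. For FAB+V against FAB (13928 genes), 86% and 99% were recovered at day 4, with 5.1% false calls, and 72% and 98% at day 6, with 7.6%. For ATAC, 5% and 58% were recovered in day 8 P-F+ against P+F+ (193768 regions, 8.7% false), 8% and 66% in FAB+V (118815 regions, 8.6% false) and 19% and 73% in FAB+P (119385 regions, 6.1% false). For region sets in FAB+V (134424 regions), 20 of 20 sets shifted by 0.1 and 0 of 20 unshifted sets reached percentile 97.5. For gene lists in day 4 FAB+P, 2 of 20 shuffled data sets gave a false list. A faster ATAC fit without a dispersion trend was set aside because of its false calls in simulated data, after exploratory counts of the real data had been seen, and is kept as an alternative. No libraries were found that differed by less than sampling noise.

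Whether same-numbered replicates belong together was checked by the correlation of their deviations from the group means, before fits were compared. With 3 pairs, every pair exceeded 0.1 in RNA day 4 P-F+ against P+F- (0.335, 0.376 and 0.289), RNA day 8 P-F+ against P+F+ (0.405, 0.187 and 0.222), RNA day 4 FAB+P against FAB (0.536, 0.47 and 0.103), ATAC day 4 P-F+ against P+F+ (0.325, 0.193 and 0.107) and ATAC day 6 (0.102, 0.209 and 0.177). There the numbers were taken to pair the libraries, and results of the fit with a replicate block stand beside those it changes. The pairing is weak in places. In RNA day 8 P-F+ against P+F+, replicate 2 correlated more with another number (0.26). In RNA day 4 FAB+P against FAB, replicate 3 reached 0.1 with another number. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

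Alternatives were quantile normalization or RLE factors, factors from regions far from a TSS, a pseudocount of 0.1, no filter on low values, DESeq2 1.42.0, a minimum fold of 2, only the compared groups in the fit, the replicate block, day 4 FAB+V libraries of both experiments together, leaving out each library in turn, a TSS distance of 20 kb, a fold enrichment of 10 or an overlap of 200 bp for H3K27ac, and summit windows of 50 and 250 bp. Motif searches planned for changed regions were not run because no genome was used here. The design asked for a count test of RNA only if counts were given. Differences of a contrast between days were tested as contrasts in the same limma and edgeR fits, and gene set tests were adjusted over all 48 of them; both were added after first results were seen.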

Results

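Mouse embryonic stem cells were driven through mesoderm towards heart, vessel and blood in serum-free culture, and 83 samples were profiled. RNA-seq of sorted populations in FAB+V (bFGF, Activin A, BMP4 and VEGF) had 2 libraries of P+F+ and 3 each of P+F- and P-F+ cells from day 4, and 3 each of P+F+ and P-F+ cells from day 8, where P is PDGFRα and F is FLK1, the VEGF receptor encoded by Kdr. RNA-seq of P+F+ cells in FAB, FAB+V and FAB+P (with PDGFAA) had 3 libraries per medium at day 4, and 3, 2 and 2 libraries at day 6 and again at day 8. ATAC-seq had 3 libraries of each of 9 time-course groups (unsorted day 0 and day 2, the 3 day 4 populations, and P+F+ and P-F+ at days 6 and 8) and, for day 4 P+F+ cells by medium, 4 libraries in FAB, 4 in FAB+P and 2 in FAB+V. H3K27ac was profiled in day 4 P+F+ cells in FAB+V and in FAB and in day 5 P-F+ cells. The series asks whether the factor ETV2 acts on blood and vessel gene enhancers before cells commit to those fates. RNA values are per-gene TPM with no known depth, and ATAC libraries had between 1947191 and 9276426 reads in regions.

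At day 4, P-F+ cells differed from P+F+ cells by strong expression of the blood and vessel programme. Fli1, an ETS factor of endothelium and blood, stood at 161.5 ± 3.06 TPM (SD, n = 3) in P-F+ cells and 1.07 ± 0.374 (n = 2) in P+F+ cells, a log2 fold change of 6.31 (SE 0.23, limma adjusted p = 1.44e-08). Of the 13 hematoendothelial factors tested, 11 rose and 0 fell (12 rose adjusted over the list alone; median 3.74, fry adjusted p = 9.13e-08). Among them were Sox7 (log2 fold change 5.57) and Sox18 (4.99). Of 19 endothelial genes, 18 rose (18 adjusted over the list alone; median 3.74, fry adjusted p = 9.13e-08). Cdh5, the junction protein VE-cadherin, rose from 0.269 ± 0.208 to 64.43 ± 12.98 TPM. Tek, the TIE2 receptor, rose from 0.219 ± 0.0582 to 50.0 ± 8.16. Etv2 itself was high in both populations, at 417.9 ± 90.2 and 218.7 ± 78.0 TPM, and did not pass the test (log2 fold change 0.96, SE 0.51, adjusted p = 0.23). Etv2 did pass in a fit of the 2 groups (0.0356), with the block in that fit (0.79, 0.0223) and with the P+F+ libraries of both experiments (1.27, 0.0223). Hapln1, a link protein of the hyaluronan matrix, had the largest increase (6.82, SE 0.35, adjusted p = 1.09e-07), and Gngt2 was at 71.8 ± 12.8 TPM in P-F+ cells and listed at 0 in both P+F+ libraries.

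Mesoderm genes were lower in day 4 P-F+ than P+F+ cells. Of 11 nascent mesoderm genes, 10 fell (10 adjusted over the list alone; median -2.25, fry adjusted p = 9.06e-05). Mesp1, a regulator of early cardiac mesoderm, was at 17.6 ± 8.59 against 265.8 ± 98.1 TPM, and Snai1 was lower too (-3.19, SE 0.30, adjusted p = 1.55e-05). Of 10 paraxial mesoderm genes, 6 fell (6 adjusted over the list alone; median -2.21, fry adjusted p = 2.36e-05), led by Pcdh8 (-4.03) and the Notch ligand Dll1 (-4.21). Among 10 cardiac transcription factors, 5 fell (5 adjusted over the list alone; median -1.23, fry adjusted p = 0.0081). Hand1 was at 5.75 ± 0.533 against 87.0 ± 26.3 TPM and Gata4 at 35.2 ± 4.80 against 173.9 ± 7.58. The Nodal inhibitor Lefty2 had the largest decrease (-5.07, SE 0.39, adjusted p = 3.04e-06). Stress genes rose as a list (2 of 8, 3 adjusted over the list alone; median 0.63, fry adjusted p = 0.00921), led by Atf3, from 7.70 ± 1.78 to 112.6 ± 26.8 TPM. Growth factor response genes fell (5 of 13; over the list alone 6 fell and 1 rose; median -0.84, fry adjusted p = 0.0358), among them Egr1 (-1.52).

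The other lists in this comparison moved less. Sox17, a factor of endoderm and also of endothelium, rose (2.6, SE 0.25, adjusted p = 1.74e-05) as 1 of 3 endoderm genes (1 adjusted over the list alone), and the endoderm list had a median of -0.08, a mean of 0.6 and a fry adjusted p of 0.00946 in the upward direction. Of 12 erythroid and blood genes 3 rose (4 adjusted over the list alone; fry adjusted p = 0.114), with the progenitor marker Cd34 at 25.9 ± 4.48 against 0.39 ± 0.103 TPM. Pluripotency genes went both ways (3 rose and 1 fell of 10; 3 and 4 adjusted over the list alone; fry adjusted p = 0.636). Calls were lower in 2 of 15 contractile genes, 1 of 3 neurectoderm genes, 1 of 9 smooth muscle genes and 1 of 8 proliferation genes (2, 1, 1 and 1 adjusted over the list alone), with fry adjusted p of 0.636, 0.238, 0.418 and 0.134. In a fit of the 2 groups these 4 lists passed, at 0.0353, 0.0384, 0.0159 and 0.00211, and the erythroid list at 0.000342 (0.0363 with a pseudocount of 0.1). Of the receptor genes used in the sort, Pdgfra was lower (-3.81, adjusted p = 0.000614) and Kdr higher (1.33, adjusted p = 0.00148) in P-F+ cells.

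Across all genes, 2637 of 14298 differed between day 4 P-F+ and P+F+ cells, 1345 higher and 1292 lower. With the replicate numbers as a block 1405 were higher and 1435 lower, so the larger side turned. The count was 1332 without P+F+ replicate 1, 1333 without P+F+ replicate 2 and 1753 without P-F+ replicate 2. The growth factor call was lost without any 1 of the 5 libraries (fry adjusted p from 0.0509 to 0.183) and with a pseudocount of 0.1 (0.0514), the cardiac factor call without P+F+ replicate 1 (0.0848) and the endoderm call without P+F+ replicate 2 (0.0669), with no filter (0.0728) and in a fit of the 2 groups (0.105).

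Day 4 P+F- and P+F+ cells were much closer, with 306 genes called (169 higher and 137 lower in P+F-). Among the genes lower in P+F- cells were the VEGF receptor and some early blood and vessel factors. Kdr was at 12.4 ± 3.79 TPM in P+F- and 238.2 ± 45.6 in P+F+ cells (-4.18, SE 0.23, limma adjusted p = 3.6e-06). Etv2 was at 8.05 ± 3.69 and 218.7 ± 78.0 (-4.65, SE 0.51, adjusted p = 0.000439). Tal1, a partner of LMO2 in blood specification, was at 0.464 ± 0.253 and 19.2 ± 3.79 (-3.79, adjusted p = 0.000553). Lmo2 also fell (-2.59, adjusted p = 0.00563; 0.0941 without P+F+ replicate 1). Of 13 hematoendothelial factors 4 were lower (7 adjusted over the list alone; median -0.79, fry adjusted p = 0.00759), and the call was lost without P+F+ replicate 1 (0.0809) or 2 (0.105). Of 19 endothelial genes 2 were lower (5 adjusted over the list alone; median -0.26, fry adjusted p = 0.291), and of 10 cardiac factors 2 (4 adjusted over the list alone; median -0.8, fry adjusted p = 0.0957). In a fit of the 2 groups these lists passed (0.0168 and 0.0204), as did contractile genes (0.0204), and with a pseudocount of 0.1 the endothelial list did (0.0341). Higher in P+F- cells were Igfbp3, which binds insulin-like growth factors (3.58, SE 0.35, adjusted p = 0.000333), and Sox3, a neural factor (2.4, SE 0.25, adjusted p = 0.000389). Gal (12.3 ± 4.61 TPM) and Cd36 (9.27 ± 1.39 TPM) were listed at 0 in both P+F+ libraries. Pdgfra did not differ (111.4 ± 16.4 against 109.2 ± 3.60 TPM). The count fell to 81 without P+F+ replicate 1, 167 without P+F+ replicate 2, 162 without P+F- replicate 3 and 200 without P+F- replicate 2.

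Between the day 4 populations that carried a single receptor, P-F+ and P+F-, 4581 genes differed (2057 higher and 2524 lower in P-F+). Etv2 was at 417.9 ± 90.2 TPM in P-F+ and 8.05 ± 3.69 in P+F- cells (5.61, SE 0.45, limma adjusted p = 1.87e-06), and Tal1 rose from 0.464 ± 0.253 to 362.1 ± 28.2 (7.96, SE 0.38, adjusted p = 2.3e-08). Of 13 hematoendothelial factors 12 were higher in P-F+ cells (13 adjusted over the list alone; median 5.27, fry adjusted p = 6.93e-09) and of 19 endothelial genes 18 (18; median 4.23, fry adjusted p = 1.51e-08). P+F- cells had more of the paraxial mesoderm list (7 of 10 genes, 8 adjusted over the list alone; median -3, fry adjusted p = 1.25e-06), with Dll1 at 301.4 ± 23.5 against 8.00 ± 2.62 TPM. The nascent mesoderm list was also higher there (7 of 11; median -1.48, fry adjusted p = 8.02e-05), with Fgf8 at 201.8 ± 18.6 against 5.05 ± 4.40. The caudal factor Cdx2 fell from 104.2 ± 16.7 to 2.09 ± 1.20 TPM (-5.16, SE 0.86, adjusted p = 0.000613). Kdr was higher (5.51, SE 0.20) and Pdgfra lower (-3.83, SE 0.51) in P-F+ cells. Hand1 was also lower there (-4.68, SE 0.44) and Gata6 higher (1.42, SE 0.28). With the replicate numbers as a block, the erythroid list (4 of 12 genes higher; fry adjusted p = 0.056 without the block) reached 0.038 and the growth factor list (3 higher and 4 lower of 13; 0.0643 without) 0.0178. The erythroid list also passed in a fit of the 2 groups (2.98e-05) and with a pseudocount of 0.1 (0.0117), and the growth factor list with quantile normalization (0.0433). In the fit of the 2 groups cardiac factors (0.00615, against 0.191), smooth muscle genes (0.0157, against 0.191) and proliferation genes (0.0266, against 0.235) passed as lower. Pluripotency genes went both ways (3 higher and 6 lower of 10; 0.056). Neurectoderm genes fell (2 of 3; 0.00207, and 0.127 with a pseudocount of 0.1), and endoderm genes (1 higher and 1 lower of 3; 0.0183) and stress genes (1 of 8; 0.0239) passed as higher. Endoderm lost its call with no filter (0.0706), in the fit of the 2 groups (0.136) and without P+F- replicate 2 (0.0505), and stress without P-F+ replicate 2 (0.0605) or 3 (0.0576) or P+F- replicate 3 (0.0981).

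**Figure D1:**
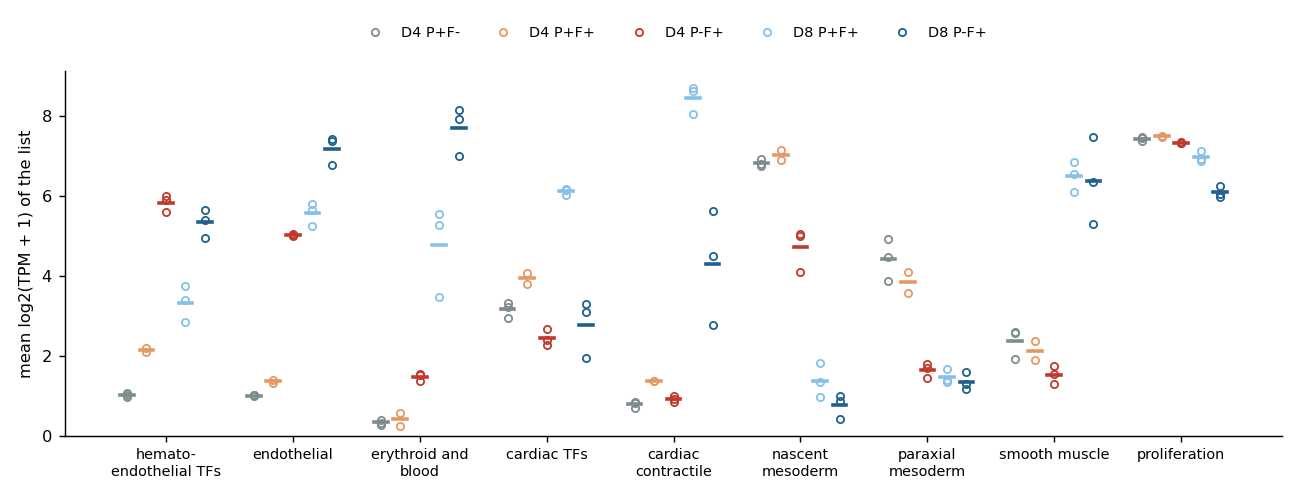
Mean log2(TPM + 1) of 9 gene lists in each library of the sorted populations in FAB+V; points are libraries, bars are group means. Hematoendothelial and endothelial levels are higher in P-F+ than P+F+ cells at days 4 and 8, and contractile genes are highest in P+F+ cells at day 8.

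By day 8, P+F+ cells had more heart transcripts and P-F+ cells more vessel and blood transcripts, though P+F+ cells also held vessel and blood transcripts. Cardiac transcription factors were all lower in P-F+ cells (10 of 10, 10 adjusted over the list alone; median -3.5, fry adjusted p = 6.14e-06), with Gata4 at 4.29 ± 2.71 against 97.8 ± 16.6 TPM (n = 3 each). Of 15 contractile genes 14 were lower (14 adjusted over the list alone; median -4.31, fry adjusted p = 1e-05). The troponin Tnnt2 fell from 1835 ± 325.2 to 171.4 ± 73.6 TPM and the calcium release channel Ryr2 by 4.44 on the log2 scale (SE 0.18, limma adjusted p = 3.03e-08). Erythroid and blood genes were all higher (12 of 12, 12 adjusted over the list alone; median 3.66, fry adjusted p = 0.000221), with the erythroid factor Klf1 at 49.4 ± 15.2 against 3.21 ± 3.08 TPM. Of 19 endothelial genes 17 were higher (18 adjusted over the list alone; median 1.6, fry adjusted p = 2.07e-05). The guidance receptor Robo4 (3.49, SE 0.25, adjusted p = 1.2e-06) led, and Cdh5 was at 669.7 ± 140.9 against 129.6 ± 29.7 TPM. Of 13 hematoendothelial factors 12 were higher (12 adjusted over the list alone; median 2.4, fry adjusted p = 1e-05), among them Runx1, needed for blood stem cell emergence (3.29, SE 0.33, adjusted p = 1.12e-05). Etv2 had returned to 2.20 ± 0.734 and 3.44 ± 3.07 TPM, with no difference called (adjusted p = 0.661). Kdr was higher (1.31, SE 0.20, adjusted p = 0.000229) and Pdgfra lower (-3.22, SE 0.51, adjusted p = 0.000274) in P-F+ cells.

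Other lists also separated the day 8 populations. All 8 proliferation genes were lower in P-F+ cells (8 adjusted over the list alone; median -0.92, fry adjusted p = 7.77e-06), with the topoisomerase Top2a at 133.7 ± 16.2 against 273.1 ± 23.2 TPM. Of 8 stress genes 7 were higher (7 adjusted over the list alone; median 1.56, fry adjusted p = 7.77e-06), including Ddit3, a factor of the unfolded protein response (2.08, SE 0.26, adjusted p = 5.13e-05). That list was written as a check of RNA or cell quality. A quality difference between the day 8 groups stays open and was not tested further. Ccl2, a monocyte chemokine, had one of the largest increases, from 1.897 ± 1.996 to 230.2 ± 34.9 TPM (6.59, SE 0.42, adjusted p = 5.1e-07). Sox17 rose in P-F+ cells as 1 endoderm gene of 3 (2.71, SE 0.22; 1 adjusted over the list alone; list median 0.82, fry adjusted p = 0.00026). Smooth muscle genes went both ways (2 higher and 3 lower of 9; fry adjusted p = 0.795), as did growth factor response genes (5 and 4 of 13; 0.646), paraxial genes (2 and 2 of 10) and pluripotency genes (2 and 2 of 10; 0.0989, and 0.0328 with the replicate block, 0.0376 with quantile normalization and 0.0345 with a pseudocount of 0.1). The nascent mesoderm list (1 higher and 3 lower) had a fry adjusted p of 0.105, and 0.0383 with the block and 0.0345 with that pseudocount, and 0 of 3 neurectoderm genes were called by limma. In all, 7595 genes were called, 2935 (38.6%) higher and 4660 lower. The median log2 fold change of all genes was -0.15, so small changes carry a direction only relative to that shift. The authors' deposited table has the larger side the other way, with 2377 genes higher and 1993 lower. The 10 most abundant genes took 7.98% to 13.85% of TPM in P-F+ and 5.07% to 5.24% in P+F+ libraries.

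P+F+ cells at day 8, set against P+F+ cells at day 4, had gained heart, vessel and smooth muscle transcripts, lost Etv2 and had less Kdr and Pdgfra. Etv2 fell from 218.7 ± 78.0 (n = 2) to 3.44 ± 3.07 TPM (n = 3; -5.82, SE 0.51, limma adjusted p = 1.62e-06). Both genes of the sort fell (fry adjusted p = 0.000167), Kdr from 238.2 ± 45.6 to 79.3 ± 12.8 TPM (-1.57, SE 0.23, adjusted p = 8.97e-05) and Pdgfra from 109.2 ± 3.60 to 27.5 ± 26.1 (-2.33, SE 0.57, adjusted p = 0.00417). All 15 contractile genes rose (15 adjusted over the list alone; median 7.41, fry adjusted p = 4.5e-07), with Myh6, the atrial myosin heavy chain, at 641.2 ± 247.8 against 0.185 ± 0.0204 TPM. Tnnt2 was listed at 0 in both day 4 libraries and at 2083, 1467 and 1954 TPM at day 8. All 19 endothelial genes rose (19 adjusted over the list alone; median 4.67, fry adjusted p = 5.88e-08), Cdh5 to 129.6 ± 29.7 from 0.269 ± 0.208 TPM. Cardiac factors that rose (5 of 10; median 2.01, fry adjusted p = 5.48e-05) included Mef2c (5.56, SE 0.35) and Nkx2-5 (5.05, SE 0.52). Smooth muscle genes (7 of 9; median 4.12, 6.53e-05) included Acta2 (7.9, SE 0.60). Erythroid genes (11 of 12; median 4.62, 5.38e-05) included the embryonic globin Hba-x, which varied from 496.7 to 4043 TPM among the 3 libraries. Day 8 P+F+ FAB+V libraries of the media experiment had far less Hba-x (values below). That difference between experiments was not tested. Hematoendothelial factors rose in 7 and fell in 1 of 13 (median 0.84, 0.000167).

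Early programmes were lost over the same interval. All 11 nascent mesoderm genes fell (11 adjusted over the list alone; median -5.4, fry adjusted p = 9.1e-08), Mesp1 from 265.8 ± 98.1 to 0.369 ± 0.638 TPM, and T, the mesoderm factor Brachyury, from 516.0 ± 143.8 TPM to values listed at 0 in all 3 day 8 libraries. Pluripotency genes fell in 6 and rose in 1 of 10 (median -1.93, fry adjusted p = 0.000137), with Pou5f1 at 1.62 ± 2.01 against 333.8 ± 149.4 TPM. Paraxial genes (5 lower and 1 higher of 10; 3.41e-06), growth factor response genes (8 of 13 lower; 1.02e-05) such as Fos (-6.85, SE 0.28), proliferation genes (6 of 8 lower; median -0.62, 0.000286) and neurectoderm genes (1 of 3 lower; 0.0383) also fell as lists. The neurectoderm call was lost without day 4 replicate 1 (0.15) or 2 (0.0581) or day 8 replicate 2 (0.196) or 3 (0.0773), with a pseudocount of 0.1 (0.076), with no filter (0.0573) and in a fit of the 2 groups (0.128). Stress genes (4 higher and 1 lower; 0.152) and endoderm genes (1 and 2 of 3; 0.202) did not pass as lists. Endoderm genes passed as lower with quantile normalization (0.000233), with a pseudocount of 0.1 (0.0283), with the block (0.0362) and without day 4 replicate 2 (0.0478), and stress genes as higher with the block (0.0208) and without day 8 replicate 1 (0.0499). Of 7988 genes called, 4869 (61.0%) were higher at day 8 and 3119 lower. After quantile normalization 3341 (41.2%) were higher and 4772 lower, and the median log2 fold change of all genes moved from 0.17 to -0.11. Small changes in this comparison carry a direction only relative to that shift.

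Etv2 and Tal1 were higher with VEGF in day 4 P+F+ cells, and 3 other genes passed the test. In FAB+V against FAB, Etv2 was at 152.8 ± 46.4 against 10.6 ± 0.668 TPM (n = 3 each; 3.68, SE 0.36, limma adjusted p = 4.77e-05), and Tal1 was at 14.1, 15.7 and 7.32 TPM in FAB+V and listed at 0 in all 3 FAB libraries (adjusted p = 6.01e-07). These were 2 of 5 calls among 13928 genes, all 5 higher in FAB+V. The others were Pcdhga3, a clustered protocadherin whose reads may be shared with its relatives (1.93, SE 0.27, adjusted p = 0.00388; 0.0764 with FAB+V libraries of both experiments), Lax1 (adjusted p = 0.000465) and Fev (adjusted p = 0.0434), both named after their values were seen. After quantile normalization 5 genes were higher and 3 lower. Of 11 hematoendothelial factors 2 rose (3 adjusted over the list alone; median 0.66, fry adjusted p = 0.0247). That call was lost without FAB replicate 1 (0.151), 2 (0.125) or 3 (0.0745) or FAB+V replicate 1 (0.0774) or 2 (0.104). The other 14 lists had 0 calls by limma, with fry adjusted p from 0.875 to 0.994. In a fit of the 6 libraries alone the endothelial list (median 0.66) and the erythroid list (median 0.96) passed as higher, each at 0.0298, and in the fit of all groups 367 genes had an unadjusted p under 0.05. Kdr (125.5 ± 26.3 against 95.9 ± 20.5 TPM) and Pdgfra (91.5 ± 13.7 against 104.0 ± 19.2) were not called.

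**Figure D2:**
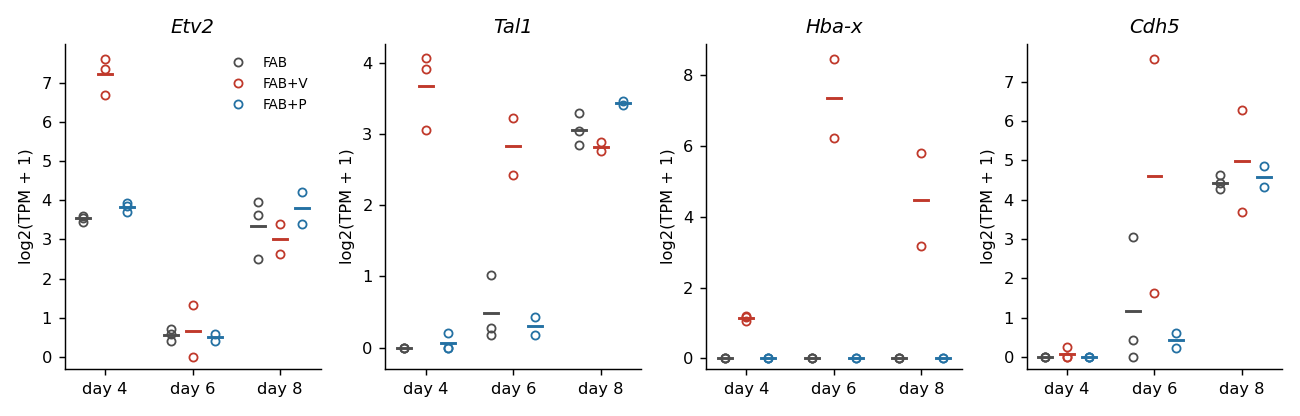
log2(TPM + 1) of Etv2, Tal1, Hba-x and Cdh5 in P+F+ cells by medium at days 4, 6 and 8; points are libraries and bars group means. Etv2 at day 4 is at 152.8 TPM on average in FAB+V and 10.6 in FAB.

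By day 6, blood transcripts were present with VEGF. The embryonic globins Hba-x (74.8 and 352.6 TPM) and Hbb-bh1 (109.1 and 474.6 TPM) and the erythroid factor Gata1 (1.06 and 3.13 TPM) were listed at 0 in all 3 FAB libraries (limma adjusted p = 1.1e-06, 7.76e-06 and 0.0136). Of 11 erythroid genes 3 rose (10 adjusted over the list alone; median 1.57, fry adjusted p = 1.12e-05), and of 11 hematoendothelial factors 2 (7 adjusted over the list alone; median 1.54, fry adjusted p = 0.00532). These were Tal1, from 0.457 ± 0.500 to 6.35 ± 2.79 TPM (2.33, SE 0.29, adjusted p = 0.00125), and Lyl1 (1.54, adjusted p = 0.0402). Lyl1 was lost with quantile normalization (0.173), a pseudocount of 0.1 (0.357) and without FAB replicate 2 (0.174) or 3 (0.12) or FAB+V replicate 1 (0.517). Etv2 was at 0.748 ± 1.06 TPM in FAB+V and 0.49 ± 0.147 in FAB, and Kdr at 37.1 ± 43.1 and 4.4 ± 1.32 (adjusted p = 0.453; 1.46e-05 without FAB+V replicate 2). The FAB+V libraries differed in endothelial genes: Cdh5 was at 190.4 TPM in replicate 1 and 2.09 in replicate 2, and the endothelial list had 0 calls by limma over all genes (16 of 19 adjusted over the list alone; median 2.36, fry adjusted p = 0.0674). Without FAB+V replicate 2 it reached 5.23e-06, the stress list 0.0451 and the sort receptors 0.000515, and the number of called genes rose from 10 to 276; without FAB replicate 2 the number was 4, and Gata1 had an adjusted p of 0.051. In a fit of these 5 libraries alone 0 genes passed, with the erythroid list at 0.102 and the hematoendothelial list at 0.526; 748 genes had an unadjusted p under 0.05 in the fit of all groups.

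At day 8, 114 genes differed between FAB+V and FAB (62 higher and 52 lower; 172 and 86 after quantile normalization). The globins Hba-x (7.99 and 54.8 TPM), Hbb-y (9.46 and 57.4 TPM) and Hbb-bh1 (4.37 and 40.9 TPM) were again listed at 0 in FAB (limma adjusted p = 0.000766, 0.00723 and 0.0149), and the erythroid list rose (3 of 11, 3 adjusted over the list alone; median 0.38, mean 1.28, fry adjusted p = 0.0496). Smooth muscle genes (1 of 9 called, 5 adjusted over the list alone; median 0.91, fry adjusted p = 0.0123) included Tagln, an actin-binding protein, at 934.5 ± 470.7 against 390.9 ± 130.8 TPM (adjusted p = 0.0471). Proliferation genes (1 of 8 called, 8 adjusted over the list alone; median 0.49, fry adjusted p = 0.0199) included Ccna2. Cox8b, a muscle subunit of cytochrome c oxidase, was lower (-3.41, SE 0.57, adjusted p = 0.0149). Contractile genes were not called over all genes (5 of 15 lower adjusted over the list alone; median -0.55, fry adjusted p = 0.0749), and Etv2 was at 7.38 ± 3.13 against 10.1 ± 5.00 TPM (adjusted p = 0.708).

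Most day 8 calls rest on single libraries. The number of genes was 18 without FAB replicate 1, 43 without FAB replicate 2, 9.7e+02 (rounded) without FAB replicate 3 and 35 without FAB+V replicate 1, and 0 in a fit of the 5 libraries alone, or 152 (52 higher and 100 lower) with the replicate block in that fit. The erythroid call was lost without FAB replicate 1 (0.1), 2 (0.0957) or 3 (0.0906) or FAB+V replicate 2 (0.658), the smooth muscle call without FAB+V replicate 1 (0.0627) and the proliferation call without FAB replicate 1 (0.0528) or either FAB+V library (0.0627 and 0.12). In the fit of the 5 libraries alone each of these 3 lists was at 0.311, and the erythroid list was at 0.128 with quantile normalization and 0.0507 with no filter. Tagln had an adjusted p of 0.46 without FAB+V replicate 1, 0.174 without FAB replicate 1 and 0.0905 without FAB replicate 2. Ccna2 had 0.278 without FAB+V replicate 1 and 0.0734 without FAB replicate 1, Cox8b 0.0636 without FAB replicate 1, and Hbb-bh1 0.0842 without FAB+V replicate 2 and 0.0619 without FAB replicate 1. With a pseudocount of 0.1 Tagln, Ccna2 and Cox8b were at 0.0684, 0.0508 and 0.0705.

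Few genes differed with PDGFAA. In FAB+P against FAB, limma called 1 gene at day 4 (the lower BC028528), 3 at day 6 (Raet1d and Ypel4 higher, Raet1a lower) and 2 at day 8 (Defb19 higher, Crygn lower), with 304, 833 and 739 genes at an unadjusted p under 0.05. All but Raet1d are named after their values were seen. Raet1d and Raet1a belong to a family of near-identical genes, so their values are uncertain. At day 4 the block gave 2 genes, and at day 8 quantile normalization gave 0. Etv2 was at 13.2 ± 1.23 against 10.6 ± 0.668 TPM at day 4 (adjusted p = 1) and Pdgfra at 97.0 ± 15.8 against 104.0 ± 19.2. No list passed, with fry adjusted p of 0.968 at day 4, from 0.758 to 0.953 at day 6 and from 0.931 to 0.998 at day 8. Without FAB replicate 1 the day 8 proliferation list passed as lower (0.023). Adjusted over the list alone, 1 endoderm gene at day 4, 3 lower nascent mesoderm genes at day 6 and 1 at day 8 were called. These counts moved with single libraries: at day 4 to 0 without FAB replicate 3 and 5 without FAB replicate 2, at day 6 to 10 without FAB replicate 2 or FAB+P replicate 1, and at day 8 to 25 without FAB replicate 2, 4 without FAB replicate 3, 23 without FAB+P replicate 1 and 8 without FAB+P replicate 2.

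In the authors' deposited tables, 95 genes were called for FAB+V at day 4, 70 at day 6 and 197 at day 8, of which 4, 5 and 49 were also called here, all in the same direction. For day 8 P-F+ against P+F+ the authors' deposited table calls 4370 genes, 4247 of them also called here.

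The set of genes higher in day 8 P-F+ than P+F+ cells was then followed in the media libraries, which were not used to choose it. In FAB+V against FAB its 2409 genes had medians of 0.03 log2 units at day 4, 0.12 at day 6 and 0.03 at day 8. The planned fry test gave an unadjusted p of 0.326, 0.00979 and 0.572. An adjustment over all 48 gene set tests, added after these values were seen, gave 0.92, 0.094 and 0.961. The 338 genes with a log2 difference of at least 2 between the day 8 populations had medians of 0.03, 0.4 and 0.13, with fry adjusted p of 0.858, 0.00203 and 0.858. At day 6 these genes stood at a mean log2(TPM + 1) of 2.653 and 2.048 in the 2 FAB+V libraries and 1.723 to 1.74 in FAB, and at day 4 at 1.46 to 1.527 in FAB+V and 1.382 to 1.386 in FAB. Much of the day 6 shift thus lay in 1 library. These 338 genes were not tested in other fits or with a library left out. Genes at least that much lower in day 8 P-F+ cells (509) had a median of -0.39 in day 8 FAB+V (fry adjusted p = 0.0189). The 1282 genes higher in day 4 P-F+ cells had medians of 0.06 at day 4 and 0.1 at day 6 (fry adjusted p = 0.459 and 0.094). The 251 of these with a log2 difference of at least 2 had medians of 0.16 and 0.46 (0.651 and 0.0912), and at day 4 stood at 1.5 to 1.618 in FAB+V and 1.316 to 1.325 in FAB. In a fit of only the 5 day 6 libraries the first set had a median of 0.13, with an unadjusted fry p of 0.0855, and without FAB+V replicate 1 a median of 0.07 (0.141).

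Regions that opened by day 2 lay at promoters more often than those that opened by day 4. Day 2 cells were unsorted and day 4 cells sorted. Whether the day 2 libraries had raised promoter signal whatever the gene did was not tested. Between day 0 and day 2, 23069 of 223565 regions changed (edgeR), 11030 more open and 12039 less open. Of these, 43.8% of the more open and 3.2% of the less open regions lay within 1 kb of a TSS, against 12.6% of those tested. A region 18782 bp downstream of the pluripotency gene Zfp42 (chromosome 8, 43288027 to 43288426, in no transcript) closed from 105 to 2 counts over 3 libraries (log2 fold change -5.66, SE 0.75, edgeR adjusted p = 5.83e-08). Of 11 pluripotency genes 10 had a less open region within 100 kb (39.1% in matched random lists, percentile 99.97). A region downstream of Pdgfra (chromosome 5, 75222846 to 75223245, in no transcript) opened from 0.724 ± 0.171 to 8.93 ± 4.31 CPM (3.58, SE 0.56, adjusted p = 2.73e-06). With factors from regions over 1 kb from a TSS, 13693 regions were more open and 9918 less open, and the median of all regions moved from -0.06 to 0.05. Leaving out day 2 replicate 1 gave 26022 regions, day 2 replicate 2 12754, day 2 replicate 3 11715, day 0 replicate 1 14439, day 0 replicate 2 15113 and day 0 replicate 3 14615.

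From day 2 to day 4 P+F+ cells, 63266 regions changed, 33368 more open and 29898 less open, and 4.7% and 18% of these lay within 1 kb of a TSS. With factors from regions over 1 kb from a TSS, 31174 (48.8%) were more open and 32746 less open. Gata4, a cardiac and mesoderm factor, gained a region 60832 bp upstream (chromosome 14, 63305892 to 63306291, in no transcript), from 0.695 ± 0.562 to 18.2 ± 1.73 CPM (4.67, SE 0.43, edgeR adjusted p = 6.21e-15). Pdgfra gained a region 2128 bp upstream (chromosome 5, 75149963 to 75150362; 3.5, SE 0.33) and Kdr one 26603 bp upstream (chromosome 5, 76004831 to 76005230; 4.44, SE 0.45). A region 730 bp upstream of Etv2 (chromosome 7, 30636382 to 30636781, in no transcript) rose from 1.83 ± 0.455 to 13.7 ± 1.52 CPM (2.88, SE 0.36, adjusted p = 4.97e-10). In a region of chromosome X inside Il1rapl1 (88043934 to 88044333), 130 counts stood against 0 on day 2.

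**Figure D3:**
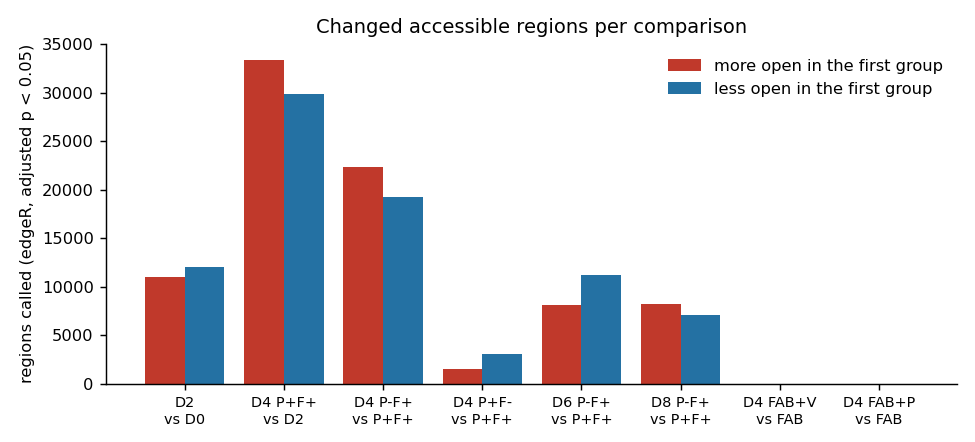
Number of regions called by edgeR (adjusted p under 0.05) in each ATAC comparison, more open and less open in the first group. Counts reach 63266 regions from day 2 to day 4 P+F+, and are 0 for both media comparisons.

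At day 4, 41614 regions separated P-F+ from P+F+ cells, 22321 more open and 19293 less open. Vessel and blood genes were among those with more open regions. A region inside Kdr, 15992 bp from its start (chromosome 5, 75962236 to 75962635), rose from 0.569 ± 0.462 to 34.8 ± 4.92 CPM (5.87, SE 0.50, edgeR adjusted p = 1.41e-15). A region upstream of Fli1 (chromosome 9, 32582095 to 32582494, in no transcript) rose from 2.56 ± 0.758 to 48.8 ± 7.18 (4.23, SE 0.32, adjusted p = 2.42e-17), and a region upstream of Cdh5 (chromosome 8, 104095686 to 104096085, in no transcript) from 1.27 ± 0.637 to 15.8 ± 1.65 (3.59, SE 0.42, adjusted p = 1.08e-10). All 14 hematoendothelial factors (68.8% in matched random lists, percentile 99.79) and all 19 endothelial genes (54.5%, percentile 100) had a more open region within 100 kb. The region 2128 bp upstream of Pdgfra closed (-2.56, SE 0.30, adjusted p = 1.49e-10).

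P+F- and P+F+ cells differed at 4667 regions, 1561 more open and 3106 less open in P+F-, and some of the latter lay near early blood and vessel factors. The region upstream of Etv2 was at 4.88 ± 0.885 CPM in P+F- and 13.7 ± 1.52 in P+F+ cells (-1.5, SE 0.30, edgeR adjusted p = 0.00123). Upstream of Tal1, a region (chromosome 4, 115049772 to 115050171, in no transcript) was at 1.59 ± 1.13 and 7.37 ± 1.67 (-2.28, SE 0.36, adjusted p = 2.19e-05). Of 14 hematoendothelial factors, 9 had a less open region within 100 kb (21.2% in matched random lists, percentile 99.99), as had 5 of 15 contractile genes (9.4%, percentile 99.32). Every library moved this count by over 1.5 times when left out: it was 1970, 2984 and 2432 without P+F+ replicates 1, 2 and 3, and 2599, 2214 and 1983 without P+F- replicates 1, 2 and 3.

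At day 6, 19320 regions differed between P-F+ and P+F+ cells, 8125 more open and 11195 less open. A region 64029 bp upstream of Lmo2 (chromosome 2, 103893766 to 103894165, in no transcript) was at 45.5 ± 20.4 CPM in P-F+ and 6.0 ± 3.17 in P+F+ cells (2.93, SE 0.36, edgeR adjusted p = 6.34e-09). A region inside Runx1 (chromosome 16, 92801597 to 92801996) was at 26.5 ± 10.8 and 3.0 ± 1.84 (adjusted p = 9.73e-09). Upstream of Hand1, a region (chromosome 11, 57904229 to 57904628, in no transcript) was at 2.16 ± 0.284 and 12.7 ± 4.0 (-2.53, SE 0.42). More open regions lay near 12 of 14 hematoendothelial factors (40.6% in random lists, percentile 99.96) and 10 of 12 erythroid genes (18.1%), and less open regions near 12 of 15 contractile genes (23.8%) and 9 of 9 smooth muscle genes (27.4%). The count was 11623 without P-F+ replicate 3 and 12287 without P-F+ replicate 2.

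At day 8, 15249 regions differed, 8197 more open and 7052 less open in P-F+ cells. With factors from regions over 1 kb from a TSS, 6997 were more open and 7527 less open, so the larger side depends on the scaling. The same Lmo2 region was at 28.6 and 2.43 CPM on average (3.29, SE 0.41, edgeR adjusted p = 2.54e-08), and a region 865 bp upstream of Gata4 (chromosome 14, 63245925 to 63246324, in no transcript) at 2.1 and 9.83 (-2.21, SE 0.42, adjusted p = 0.000112). A region 26305 bp upstream of Has2, a hyaluronan synthase (chromosome 15, 56720651 to 56721050, in no transcript), had 3 counts in P-F+ and 166 in P+F+ cells (-5.35, SE 0.63, adjusted p = 6.17e-09). Less open regions lay near 10 of 10 cardiac factors (42.5% in random lists) and 14 of 15 contractile genes (17.2%), and more open regions near 10 of 12 erythroid genes (25.9%, percentile 99.99). Of the more open regions 48.7% lay within 1 kb of a TSS, against 16.1% of the less open and 12.6% of those tested. The count was 7653 without P-F+ replicate 3 and 8683 without P+F+ replicate 2.

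No region passed between media in day 4 P+F+ cells in the main fits, while some alternative fits called regions, with counts given under processing below. edgeR called 0 of 134424 regions for FAB+V against FAB (2 against 4 libraries; 6752 at an unadjusted p under 0.05, smallest adjusted p 0.901) and 0 for FAB+P against FAB (4 against 4; 6132, smallest adjusted p 1), and DESeq2 called 0 for both. In simulated data of FAB+V, with changes planted only above a minimum mean count, 66% of log2 changes of 2 and 8% of changes of 1 were recovered. Smaller changes were thus not detectable region by region, and recovery in regions with fewer reads was not simulated. The authors' deposited table for FAB+V against FAB calls 27 of 148314 regions (16 higher and 11 lower), of which 7 (6 higher in FAB+V) were more open in day 4 P-F+ cells here, 1 (1 higher) at day 6 and 0 at day 8, and 3 (1 higher), 6 (1 higher) and 3 (0 higher) were less open.

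Sets of regions chosen in the time course were shifted by small amounts in FAB+V. The sets more open at day 6 and less open at days 6 and 8 shifted the same way in FAB+P, which holds no VEGF. The other sets did not. Both contrasts subtract the same 4 FAB libraries, so a like shift in both is not independent evidence. Regions more open in day 4 P-F+ than P+F+ cells had a median log2 fold change of 0.08 in FAB+V against FAB (5891 regions, random sets 0.01, percentile 100). Those more open at day 6 had a median of 0.07 (2340 regions, random sets 0, percentile 100). In the day 4 set FAB levels relative to matched regions were -0.099, -0.093, -0.05 and 0.147. The FAB library at 0.147 lay above both FAB+V libraries (0.055 and 0.058). Regions more open at day 8 had a median of -0.12 (5500 regions; random sets -0.08, percentile 0), and over 1 kb from a TSS -0.03 (percentile 60.42). Regions less open in P-F+ cells had medians of 0.1 at day 4 (17590 regions), -0.34 at day 6 (8419 regions) and -0.22 at day 8 (5278 regions). Single FAB libraries add to these shifts. In the day 4 set FAB levels were -0.275, 0.018, 0.12 and 0.176, with a FAB+V mean of 0.115. FAB replicate 4 stood at 0.426 in the day 6 set and 0.324 in the day 8 set. The other FAB libraries reached at most 0.029 and 0, with FAB+V means of -0.22 and -0.172. In FAB+P against FAB the sets more open at day 4, 6 and 8 had medians of -0.01 (percentile 15.2), 0.03 (99.96) and 0.35 (100; random sets 0.06), and the less open sets -0.1, -0.15 and -0.06 (percentile 0 for each). The 0.35 is carried by 2 of 4 libraries: their levels relative to matched regions were -0.17, -0.128, 0.231 and 0.587. Random sets describe these libraries only: with 2 against 4 libraries an exact permutation test of the per-library levels cannot give a p under 0.0667, and no set passed (adjusted p from 0.267 to 0.667), nor did any in FAB+P with 4 against 4 libraries (smallest possible 0.0286; adjusted p from 0.514 to 1). A fry test added after the data were seen passed no set in either medium (adjusted p from 0.171 to 0.754 in FAB+V, 0.759 in FAB+P). With FAB+V replicates 1 to 3 of the time course added, it gave 0.0117 for the sets more open at day 4, more open at day 6 and less open at day 6. Those replicates were the P+F+ side in choosing the day 4 sets, and they come from another experiment. The value is therefore no independent test of VEGF.

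**Figure D4:**
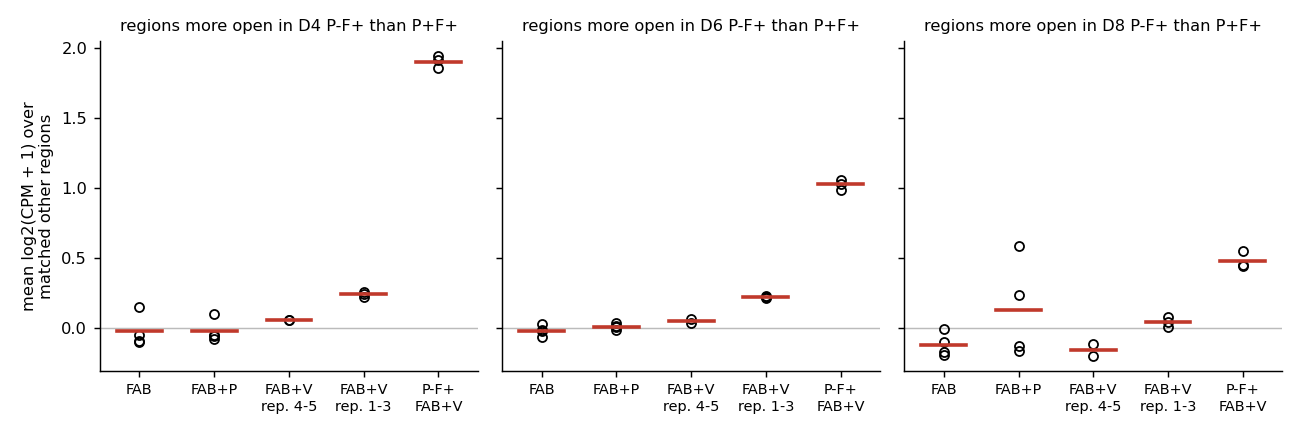
Mean log2(CPM + 1) of regions more open in P-F+ than P+F+ cells at day 4, 6 and 8, relative to matched other regions, in each day 4 library; points are libraries, bars group means. FAB+V replicates 1 to 3 and P-F+ belong to the time course that chose the regions; the other groups do not.

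Sites more open in P-F+ than P+F+ cells at day 4 overlapped day 5 P-F+ H3K27ac more often than matched regions, though most overlapped no peak. The day 4 P+F+ mark covered few of them. These sites were chosen as less open in day 4 P+F+ cells, so the choice itself favours a low share there. It likewise favours a higher share among the less open sites. No list came from day 5 P+F+ or day 4 P-F+ cells, so sort and day cannot be told apart. Of 22321 more open regions, 3056 (13.69%, Wilson 95% interval 13.25 to 14.15) overlapped a day 5 peak, against 5.56% of matched random regions (percentile 100), and 0.82% (0.71 to 0.94) overlapped a peak of day 4 P+F+ cells in FAB+V, against 3.12% (percentile 0). Of the regions less open in P-F+ cells 4.77% (4.48 to 5.08) overlapped that day 4 list, against 3.08%. At a fold enrichment of at least 10 this share was 1.38% against 1.25% (percentile 95.2). Of regions more open at day 6, 10.9% (10.25 to 11.6) overlapped a day 5 peak, against 7.27%, and at day 8 43.21% (42.14 to 44.29), against 39.15%. With an overlap of 200 bp these were 4.66% against 4.3% (percentile 96.09) and 20.52% against 20.57% (percentile 42.79). Of 14 hematoendothelial factors, 13 had a marked region assigned at day 5, 2 (Etv2 and Runx1) at day 4 in FAB+V and 1 (Etv2) at day 4 in FAB. Of 15 regions assigned to Tal1, 10 were marked at day 5 and 0 in either day 4 list, and of 27 assigned to Gata4, 9 were marked at day 4 in FAB+V, 4 in FAB and 0 at day 5. Each list seems to pool its replicates, so differences between lists carry no test; the lists hold 8891, 6103 and 14831 distinct intervals at a fold enrichment of at least 5 for day 4 FAB+V, day 4 FAB and day 5.

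**Figure D5:**
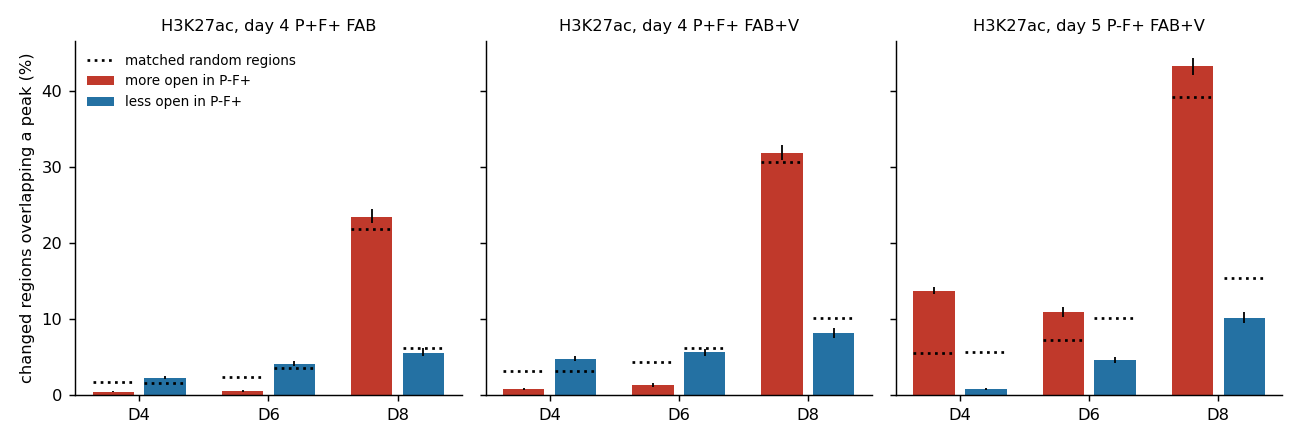
Share of regions more or less open in P-F+ than P+F+ cells at days 4, 6 and 8 that overlap an H3K27ac peak of each list, with Wilson 95% intervals; dotted lines are matched random regions. At day 4, 13.69% of more open regions overlap a day 5 P-F+ peak and 0.82% a day 4 P+F+ FAB+V peak.

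Of the summits in day 8 P-F+ libraries, 59.6% on average lay within 100 bp of a summit of a day 4 P-F+ library and 55.9% of a day 4 P+F+ library, against 61.6 ± 12.8% within the group. Libraries that the labels give the same condition differed between experiments. Day 4 P+F+ FAB+V cells of the sorted RNA set and of the media set differed in 130 of 12078 genes, and ATAC replicates 1 to 3 and 4 to 5 in 5371 of 172042 regions, so comparisons were kept within an experiment. These counts ranged with single libraries left out, down to 7 without replicate 1 of the sorted RNA set and 140 without replicate 4 of the media ATAC set.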

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

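The tests of differences between days and their alternative fits, the test of endothelial genes between the day 6 FAB+V libraries and the splits of the RNA libraries were chosen after the results were seen.

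The contrast of P-F+ and P+F+ cells changed between days, by a test of the difference itself. RNA differed in 4264 of 14298 genes between day 8 and day 4 (1735 higher and 2529 lower; 5980 at an unadjusted p under 0.05; 2759 without day 4 P+F+ replicate 2). The P-F+ advantage in vessel genes shrank as P+F+ cells gained them: the difference in log2 fold change was -2.59 for Sox18, -3.32 for Cdh5, -3.31 for Esam and -2 for Cd34, and the hematoendothelial and endothelial lists fell with fry adjusted p of 0.000357 and 0.00022. The P+F+ advantage in heart genes grew, with -2.1 for Gata4 and fry adjusted p of 0.00124 for cardiac factors and 0.000507 for contractile genes. Mesoderm genes, lower in P-F+ cells at day 4, gave 2 for Snai1, 5.25 for Dll1 and 4.94 for Tbx6, with lists rising at 0.00522 (nascent) and 0.000357 (paraxial). Fos gave 3.31, Esrrb -1.97 and Ccnb1 -0.65, the proliferation list fell (0.000507) and the stress list rose (0.00818).

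In chromatin, the same contrast changed between day 4 and day 6 at 14278 regions (4784 higher and 9494 lower) and between day 4 and day 8 at 16035 regions (6867 and 9168). For the media, FAB+V against FAB changed in 3 genes between day 4 and day 6 (433 at an unadjusted p under 0.05 by limma) and in 8 between day 4 and day 8 (1561); these counts were 163 without day 6 FAB+V replicate 2 and 92 without day 8 FAB replicate 3. The difference of Etv2 between FAB+V and FAB was smaller after day 4, with a change of -3.59 by day 6 (limma adjusted p = 0.0147; 0.428 with a pseudocount of 0.1) and of -4.01 by day 8 (0.00328; 0.236 with a pseudocount of 0.1). The day 6 call was lost without day 4 FAB replicate 3 (0.0536) or day 4 FAB+V replicate 1 (0.066) or 2 (0.0726). The difference of the erythroid list between FAB+V and FAB was larger at day 6 than at day 4 (fry adjusted p = 0.000434).

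Among groups of 4 samples, 1 FAB+P ATAC library lay far from the other 3 on 2 of 22 tests, where chance flags about 1 in 20. FAB+P replicate 4 had a TMM factor of 0.842 against 1.01, 1.018 and 1.032 (gap over range 0.884) and a level of regions more open in day 4 P-F+ cells of 0.099 against -0.078, -0.063 and -0.052 (0.853).

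Promoters made up 48.7% of the regions more open in day 8 P-F+ than P+F+ cells, against 12.6% of those tested. Scaling between libraries was argued against only weakly: with factors from regions over 1 kb from a TSS the share was 46.5%. Of the 14524 regions called with those factors, 14034 were shared with the main fit, so the share had little room to move. Promoter signal raised in the day 8 P-F+ libraries whatever the gene does cannot be told apart from regulation, because promoter regions of genes with lower RNA had a median log2 fold change of 0.04 (0.036) with 1143 more open and 564 less open, against 0.28 (0.284) for genes with higher RNA.

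Blood transcripts appeared in day 6 FAB+V libraries, with an erythroid list median of 1.57. Scaling was argued against by a median of 1.4 after quantile normalization. Cells of another type among the sorted cells cannot be told apart from a response to VEGF. Hba-x, Hbb-bh1 and Gata1 were present in both FAB+V libraries, so such cells in 1 library alone would not give these values. The library with more Hba-x had less of the endothelial genes (median log2 difference -4.69), but blood cells carry few of these, so the bound set for this test was wrong and blood cells among the sorted cells stay open. A response of P+F+ cells to VEGF also stays open, found and tested on the same 5 libraries.

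With FAB+V replicates 1 to 5 together against FAB, 1328 regions were called, where replicates 4 and 5 alone gave 0. A difference between experiments cannot be told apart from a VEGF response: over 6 choices of FAB libraries, a mean of 65.1% of the regions kept their direction in separate libraries (SD 11.2, from 48.4% to 77.2%).

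Other splits of the libraries were counted in fits of the 2 groups. The real split alone gave as many calls (1 of 10) for RNA of day 4 P-F+ against P+F- (6035, highest other 1) and of day 8 P-F+ against P+F+ (5346, highest other 2), and for ATAC of day 2 against day 0 (37166, highest other 0), day 4 P+F+ against day 2 (63566, 0), day 4 P-F+ (49289, 0) and P+F- (10021, 0) against P+F+, and P-F+ against P+F+ at day 6 (15257, 0) and day 8 (11345, 0). For RNA of day 4 FAB+V against FAB, 3 of 10 splits gave as many (4, highest other 4), and for FAB+P 10 of 10 (0, highest other 3). With 10 splits no share under 0.05 was possible. For ATAC of FAB+P against FAB the real split gave 0, so all 35 splits gave as many by construction, which decides nothing, as for FAB+P in RNA. Of the other splits 3 gave any region, the highest 1568 (FAB+P replicates 1 and 2 with FAB replicates 2 and 3), which points to some structure among these libraries besides medium.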

How the results depend on the processing

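Alternatives for the fits were planned, except tests without a dispersion trend, factors from distal regions, the block in fits of 2 groups, the settings for gene lists, gene sets, differences between days and the same condition, and their left-out libraries, which were tests chosen after the data were seen. No named gene, gene list or named region that passed its test turned direction. The pluripotency list of day 4 P-F+ against P+F- (median -1.33 in both fits) leaned down (fry adjusted p = 0.056) and passed as higher in a fit of 2 groups (0.0302), but as lower without P-F+ replicate 3 (0.0356) or P+F- replicate 1 (0.0467). The larger side of a count turned in 25 of 253 alternatives, 4 of them with other scaling between libraries (P+F+ day 8 against day 4 in RNA, and day 2 against day 0, day 4 P+F+ against day 2 and day 8 in ATAC, with values in the report). Of values for counts, sets and shares, 219 kept their side or lay within the limit, 107 moved and 2 weakened. With a library left out, named genes kept their status, called or not, in 1780 cases, weakened in 141 and strengthened in 3. For gene lists these were 844, 32 and 9, and for named regions 484 and 14. With other settings they were 2119, 94 and 11 for genes, 777, 18 and 29 for lists (besides the 1 that turned), and 484 and 3 for regions. Genes and lists not called in either fit count as keeping their status. The cause was not tested where none is given. Where 1 library remained in a group, it was assumed to vary like the others.

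Quantile normalization gave 8 genes in FAB+V at day 4, 4 at day 6 and 258 at day 8, and in FAB+P 3 at day 4 and 0 at day 8. No filter on low values gave 16 and 219 genes for FAB+V at days 6 and 8, and 2, 10 and 14 for FAB+P at days 4, 6 and 8. A pseudocount of 0.1 gave 8 and 22 genes for FAB+V at days 4 and 8. A fold change of at least 2 gave 1301 genes for day 4 P-F+ against P+F+, 1898 against P+F-, 3291 for day 8, 3978 for P+F+ day 8 against day 4 and 62 for FAB+V at day 8. Both RNA experiments together gave 4288 genes for day 4 P-F+ against P+F+, 842 for P+F- (571 higher and 271 lower) and 11 for FAB+V. Fits of 2 groups, which leave fewer libraries to estimate spread, gave 0 genes for FAB+V and FAB+P at days 6 and 8 and for FAB+P at day 4. They gave 37166 regions for day 2 against day 0, 10021 for P+F- against P+F+ and 5 for FAB+V. For P+F- against P+F+, DESeq2 gave 3054 regions and no dispersion trend 10698. FAB+V replicates 1 to 5 gave 1328 regions.

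Genes higher in day 8 P-F+ cells had a median of 0.126 in day 6 FAB+V in a fit of 2 groups, and regions more open at day 8 one of -0.0254 over 1 kb from a TSS. H3K27ac shares at a fold enrichment of 10 and at an overlap of 200 bp were 4.66% and 6.52% (day 5, more open at day 4), 0.28% and 0.35% (day 4 FAB+V, more open), 1.38% and 2.22% (day 4 FAB+V, less open), 4.06% and 4.66% (day 5, more open at day 6) and 29.23% and 20.52% (day 5, more open at day 8), as stricter rules count fewer peaks. Among these, 1.38% stood against 1.25% of matched random regions (percentile 95.2), 4.66% of day 6 regions against 4.3% (96.09) and 20.52% against 20.57% (42.79). Summit sharing of day 8 P-F+ was 44.8%, 73.6% and 45.4% with day 4 P-F+ and 42.4%, 68.4% and 42.4% with day 4 P+F+ at 50 bp, 250 bp and the top 20000.

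Leaving out 1 library gave 1332 to 2266 genes for day 4 P-F+ against P+F+, 81 to 289 for P+F-, 4 to 276 for FAB+V at day 6, 18 to 9.7e+02 (rounded) at day 8, and 0 to 5, 4 to 10 and 2 to 25 for FAB+P at days 4, 6 and 8. Regions ranged from 11715 to 26022 (day 2 against day 0), 1970 to 2984 (P+F-), 11623 to 20334 (day 6), 7653 to 17691 (day 8) and 0 to 8 (FAB+P). The day 6 gene set median ranged from 0.07 to 0.162, and the same condition differed in 7 to 55 genes and 140 to 5776 regions.

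In the 5 comparisons taken as paired the replicate block changed no call besides those given in the report and Esrrb (0.05) and Pdgfrb (0.0502) at day 8. Elsewhere the rule for pairing was not met or had too few pairs, with correlations from -0.369 to 0.55. Day 4 P+F+ RNA had 2 libraries, whose pairs gave 0.401 and 0.185 with P-F+ and 0.55 and 0.321 with P+F-. A pairing there stays open, and the main fits of those comparisons leave it out. The block gave 451 genes for FAB+V at day 8 (erythroid list 0.0512), put the day 4 FAB+V hematoendothelial list at 0.0545 and the endoderm and stress lists of P+F+ day 8 against day 4 at 0.0362 and 0.0208, and gave 25147 regions for day 2 against day 0, 65628 for day 4 P+F+ against day 2, 5567 for P+F-, 16901 for day 8 and 50 for FAB+P; in none of those with 3 or more pairs did every sample correlate best with its own number. In fits of 2 groups the block gave 4108 genes for day 4 P-F+ against P+F+, 1055 for P+F- and 0 for FAB+V at day 6 and FAB+P at days 4, 6 and 8. Motif searches were not run. Few small ATAC changes were recovered in simulated data, at a median of 3 to 15 reads per region. Depth, number of libraries and spread were not separated as causes.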

Other observations

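The tests of FAB cells at day 8 against day 6 were chosen after the values were seen.

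P+F+ cells in FAB, with no added VEGF, had more early blood and vessel transcripts, and more heart transcripts, at day 8 than at day 6. Etv2 rose from 0.49 ± 0.147 to 10.1 ± 5.0 TPM (n = 3 each; log2 fold change 2.78, SE 0.36, limma adjusted p = 8.67e-06), Kdr from 4.4 ± 1.32, where day 4 FAB cells had 95.9 ± 20.5, to 53.2 ± 11.7 (3.33, SE 0.50, adjusted p = 3.64e-05) and Tal1 from 0.457 ± 0.500 to 7.41 ± 1.31 (2.57, SE 0.26). Of 11 hematoendothelial factors 10 rose (over the list alone the same 10 rose and Runx1, at -0.33, fell; fry adjusted p = 0.000408), and of 19 endothelial genes 15 (15; median 2.61, fry adjusted p = 0.0389). The unadjusted fry value of the endothelial list, 0.0219, was 0.0615 without day 6 replicate 2, 0.0675 without day 6 replicate 3 and 0.0551 without day 8 replicate 1. Proliferation genes (7 of 8; fry adjusted p = 0.000408), nascent mesoderm genes (5 fell and 1 rose of 11; 0.0029) and growth factor response genes (5 of 13; 0.0389) fell, and contractile genes (8 rose and 1 fell of 15; 0.000638) and cardiac factors (5 of 10; 0.00499) rose, among 6280 genes called (3484 higher and 2796 lower).

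In day 8 P-F+ cells the interferon-induced gene Rsad2 was at 62.4 ± 22.8 TPM against 1.23 ± 0.85 in P+F+ cells (4.84, SE 0.32, limma adjusted p = 7.08e-07). Rpl26 was at 659.7 ± 42.6 against 1.84 ± 1.52 TPM (8.05, SE 1.83, adjusted p = 0.00285) and Beta-s at 734.7 ± 270.8 against 43.7 ± 38.5 (5.43, SE 1.17). Rpl26 has pseudogenes and Beta-s has globin paralogs, and sharing of reads with these was not tested, so both values are uncertain.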
